A study of Rattus norvegicus with 40 samples.

How the data were processed

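Pars tensa RNA of male rats was measured at 9 times after perforation of the left tympanic membrane and in unperforated controls, on 40 arrays. Per the labels' protocols, the membrane was perforated with a 23 gauge needle, the pars tensa was dissected off the malleus handle and annulus, samples with an RNA integrity number of 6 or below were rejected, and RNA of 6 rats was pooled per array. The protocols describe 18 rats and 3 pools per time point, while the labels list up to 6 pools, so pools numbered above 3 may share rats with pools 1 to 3.

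The deposited scanner files hold intensities made with Agilent Feature Extraction 9.5.3.1 from 1-colour scans, per the file headers. The processed signal intensity in them had been background-subtracted and detrended within each array by that software and not scaled between arrays, per the file headers. The deposited value table equals the net signal intensity of the scanner files on 100% of spots, within 0.1% or 0.01 units. Each array held 45018 spots, of which 43379 were not controls, for 41012 distinct probes. The software marked 3799 spots over all arrays as outliers and 0 as saturated, and marked spots were left out. The headers gave 10 slides and 2 scan batches.

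Spots of 1 probe were averaged as log2 of the processed signal, and each array was scaled to its 75th percentile. Probes were given current symbols by accession (10735), symbol (5571) or synonym (3729), and 20977 kept the file's name. A gene was represented by its probe with the highest mean over the 40 arrays and was tested where that probe was well above background on at least 3 arrays. This left 26133 of 35581 genes and transcripts, 12335 of them with a symbol and 241 with a missing value. Probe positions are those of build rn3.

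All arrays entered 1 limma fit (R 4.3.3, limma 3.58.1) with a mean per group and empirical Bayes moderation with an intensity trend. Contrasts were each time against control, 72 h against 12 h, 168 h against 72 h, 168 h against 12 h and 12 h with 36 h against 24 h with 48 h, beside an F test among the 10 groups. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. There were 54 fixed lists of pathways and cell types with 1082 genes. They were tested with camera at a preset correlation of 0.01, adjusted over the 486 tests against control, the 162 between times and the 54 of the last contrast. An estimated correlation and fry were the alternatives. List members were also adjusted over the list alone. Lists overlap, and membrane cells express members of several.

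Genes named were the 5 largest rises and falls per time among genes with a symbol, past the threshold, well above background on every array of the brighter group and with every perforated array beyond every control array, then the 3 members of each list with the smallest F test p, and 30 genes chosen whatever their values, not all of which are reported. Of those 30, Btc and Fgf10 were not tested and Krt6a and Krt16 were not on the array. The tests, lists, rule for names and alternatives other than those named below as later were set before the data were examined.

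On simulated data with the arrays' own spread, log2 changes of 1, 2 and 3 at 72 h were called for 11 of 67, 46 of 67 and 56 of 66 genes, and 11 of 132 calls (8.33%) were false. A shifted list had a camera adjusted p of 4.5e-32 and 0 of 699 other tests passed, but genes were independent, leaving correlated lists untested. Of the other 8 times, 144 h gave 68 false calls. Signal over background differed between arrays, with a 75th percentile of 6.96 on 144 h pool 4, 26.9 on 120 h pool 4 and 21.1 on control pool 2.

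Scaling moved the median of all genes. Over the comparisons it ran from -0.28 to 0.10 here, from -0.42 to 0.10 with normexp background correction, from -0.05 to 0.03 with quantile normalization, from -0.19 to 0.16 with each array scaled to its median, from -0.42 to 0.04 with the value table and from -0.32 to 0.33 with the percentile over 3296 probes well above background on all arrays. Controls shared a slide with 12 h arrays alone, so the other times could not be compared with controls within a slide. The pool numbers were checked for pairing by the correlation of deviations from group means: in 2 of 12 pairs of groups every same-numbered pair exceeded 0.1 (24 h with control and 168 h with 72 h). Alternatives were other background corrections, scalings, filters and probe choices, other variance models, fewer groups or pools, blocks by slide, scan batch and pool number, array weights, and leaving out arrays.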

Results

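The pars tensa, the thin vibrating part of the eardrum, was collected from male rats whose left membrane had been pierced with a needle and from rats left unperforated, and its RNA was hybridised to 1-colour whole-genome arrays. Groups were taken at 12 h, 24 h, 36 h, 48 h, 72 h, 96 h, 120 h, 144 h and 168 h after perforation. Each array carried RNA of 1 pool of 6 rats. There were 6 control arrays, 5 at 12 h, 4 each at 24 h, 36 h, 72 h, 120 h and 144 h, and 3 each at 48 h, 96 h and 168 h. The share of probes well above background was 18.8% on 144 h pool 4, 36.0% on 120 h pool 4 and 32.4% to 71.5% on the other 38. Those 2 arrays correlated less with their own groups (0.189 and 0.698) than the other 38 did (lowest 0.864) and are called the arrays that stand apart. Every comparison against control asks which genes differed from unperforated membrane at that time after wounding. Values in parentheses after a gene are log2 differences ± standard error between the groups named, and the largest rises and falls are the 5 with a gene symbol past the threshold, well above background on every array of the brighter group and with all perforated arrays beyond every control array. "At least" marks a gene not well above background on any array of the dimmer group, for which the fold is a lower bound. List counts are of measured members, in-list counts adjust over the list's members alone, medians are of their log2 changes, and "with bounds" sets members below background at their bound. A highest value, peak or lowest median is that of the group means, and times were compared by test only where stated. Array number limits precision, and p-values use the spread of all arrays, slides and weak ones included.

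**Figure D1:**
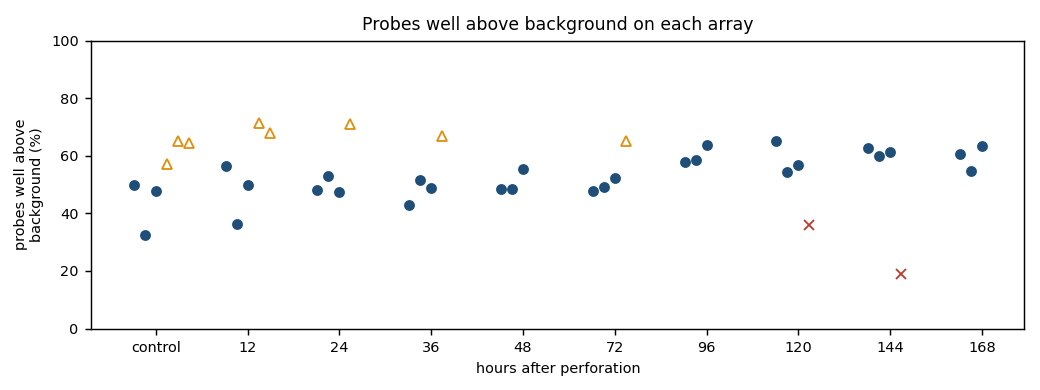
Signal of the 40 arrays by group, with the percent of probes well above background, 1 point per array, blue for pools 1 to 3, orange triangles for pools numbered above 3 and red crosses for the 2 arrays that stand apart. The cross at 144 h sits at 18.8% and the one at 120 h at 36.0%.

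At 12 h after perforation genes of keratinocyte activation, inflammation and stress were up. Stefin A2 (Stfa2, a cysteine protease inhibitor, probe at chromosome 11, 66480943 to 66481002 of build rn3) rose at least 168-fold, adjusted p = 1.5e-16, and its paralogs Stfa2l1 and Csta3 rose at least 70.2-fold and at least 51.1-fold, with cross-hybridisation among these related genes not examined. The natriuretic peptide gene Nppb (chromosome 5, 165073752 to 165073811) rose by 8.09 ± 0.49, adjusted p = 2.2e-14 and the cytokine gene Il24 by 7.26 ± 0.38, adjusted p = 1.9e-16. Prostaglandin synthase 2 (Ptgs2) rose at least 30.0-fold, interleukin 6 (Il6) at least 21.7-fold and the metalloreductase gene Steap1 at least 15.1-fold. The 5 largest falls were in Adh7 (-3.73 ± 0.41), Bbox1 (-3.40 ± 0.46), Sostdc1 (-3.13 ± 0.51), Them5 (-3.13 ± 0.37) and Cyp2f4 (-3.01 ± 0.41), which encode a retinol-oxidising alcohol dehydrogenase, the last enzyme of carnitine synthesis, a BMP and WNT antagonist, an acyl-CoA thioesterase and a cytochrome P450. In the keratinocyte activation list 8 of 12 rose and 1 fell (8 and 1 in-list, median 2.84, camera adjusted p = 2.8e-13), led by the urokinase receptor Plaur (5.29 ± 0.53) and the envelope transglutaminase Tgm1 (2.85 ± 0.36). Of inflammatory cytokines 4 of 13 rose (5 in-list, median 0.53 or 0.00 with bounds, camera adjusted p = 1.6e-05). Of NF-kB feedback and targets 11 of 15 rose (11 in-list, median 1.29, camera adjusted p = 8.4e-17), including the adhesion receptor Sele (2.94 ± 0.32). Of chemokines 9 of 25 rose (11 in-list, median 0.72, camera adjusted p = 1.3e-09). Of antimicrobial defence genes 7 of 15 rose (9 in-list, median 1.46, camera adjusted p = 1.2e-14), among them lipocalin 2 (5.41 ± 0.37). In the EGF family of ligands and receptors 5 of 13 rose (5 in-list, median 0.43, camera adjusted p = 5.4e-08). The ligands Areg (6.48 ± 0.53), Epgn (3.98 ± 0.28), Nrg1 (3.65 ± 0.27), Hbegf (3.07 ± 0.41) and Ereg (2.38 ± 0.30) rose, while Egf (-0.50 ± 0.60), Tgfa (0.46 ± 0.48) and Egfr (0.16 ± 0.48) did not pass. Of immediate early genes 7 of 26 rose and 1 fell (10 and 1 in-list, median 0.75, camera adjusted p = 3.1e-05). There Fosl1 (4.91 ± 0.45) rose and Klf4 (-1.18 ± 0.33) fell. Of unfolded protein and heat shock genes 7 of 24 rose (11 in-list, median 1.01, camera adjusted p = 7.5e-06, adjusted p = 0.333 with an estimated correlation). The chaperone genes Hspa5 (1.63 ± 0.37) and Hsph1 (2.34 ± 0.44) rose. In the oxidative stress response 4 of 21 rose and 3 fell (5 and 3 in-list, median 0.10, camera adjusted p = 0.0223). Metallothionein Mt1 (2.62 ± 0.25), Txnrd1 (2.04 ± 0.28) and Hmox1 (1.95 ± 0.42) rose. Of interferon response genes 3 of 23 rose (3 in-list, median 0.56, camera adjusted p = 0.0140, adjusted p = 0.504 with an estimated correlation), namely Ifit1 (1.78 ± 0.43) and Gbp2 (1.25 ± 0.36) and 1 more. Cell cycle and mitosis genes had not risen: 1 of 30 fell (0 in-list, median -0.14, camera adjusted p = 0.403), and the 1 that fell was Kif20a (-0.88 ± 0.28). Of the circadian clock list 3 of 17 rose and 5 fell (4 and 5 in-list, median -0.09, camera adjusted p = 0.513). There Dbp (-2.63 ± 0.49) fell and Cry1 (1.31 ± 0.30) rose. The time of day of perforation was not given, so for clock genes a daily cycle cannot be told apart from wounding. Of skeletal muscle markers 0 of 14 passed limma's test (0 in-list, 5 at an unadjusted p under 0.05, median -1.15 or -0.65 with bounds, camera adjusted p = 0.00776, adjusted p = 0.468 with an estimated correlation). Myl11 (-2.01 ± 0.70), Tnnt3 (-0.15 ± 0.37) and Myh4 (-1.78 ± 0.80) did not pass. In all, 2027 of 26133 genes passed limma's test with Benjamini-Hochberg adjustment, of which 1120 genes were higher and 907 lower, and the median of all genes lay at -0.12. Among the 12 h changes named, the adjusted p was at most 0.0446 (Kif20a). On slides 7 and 4, with both groups, 2026 and 2025 of 2027 genes and 27 of 27 lists kept direction. The same arrays made the calls, so this is no separate test. At 12 h the count was 3710 without 144 h pool 4 and 5096 without both arrays that stand apart. At 12 h, slide as a fixed block gave 2118 genes, and 27 of 27 list calls kept direction and passed. That block kept 1475 of the 2027 gene calls in the same direction.

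**Figure D2:**
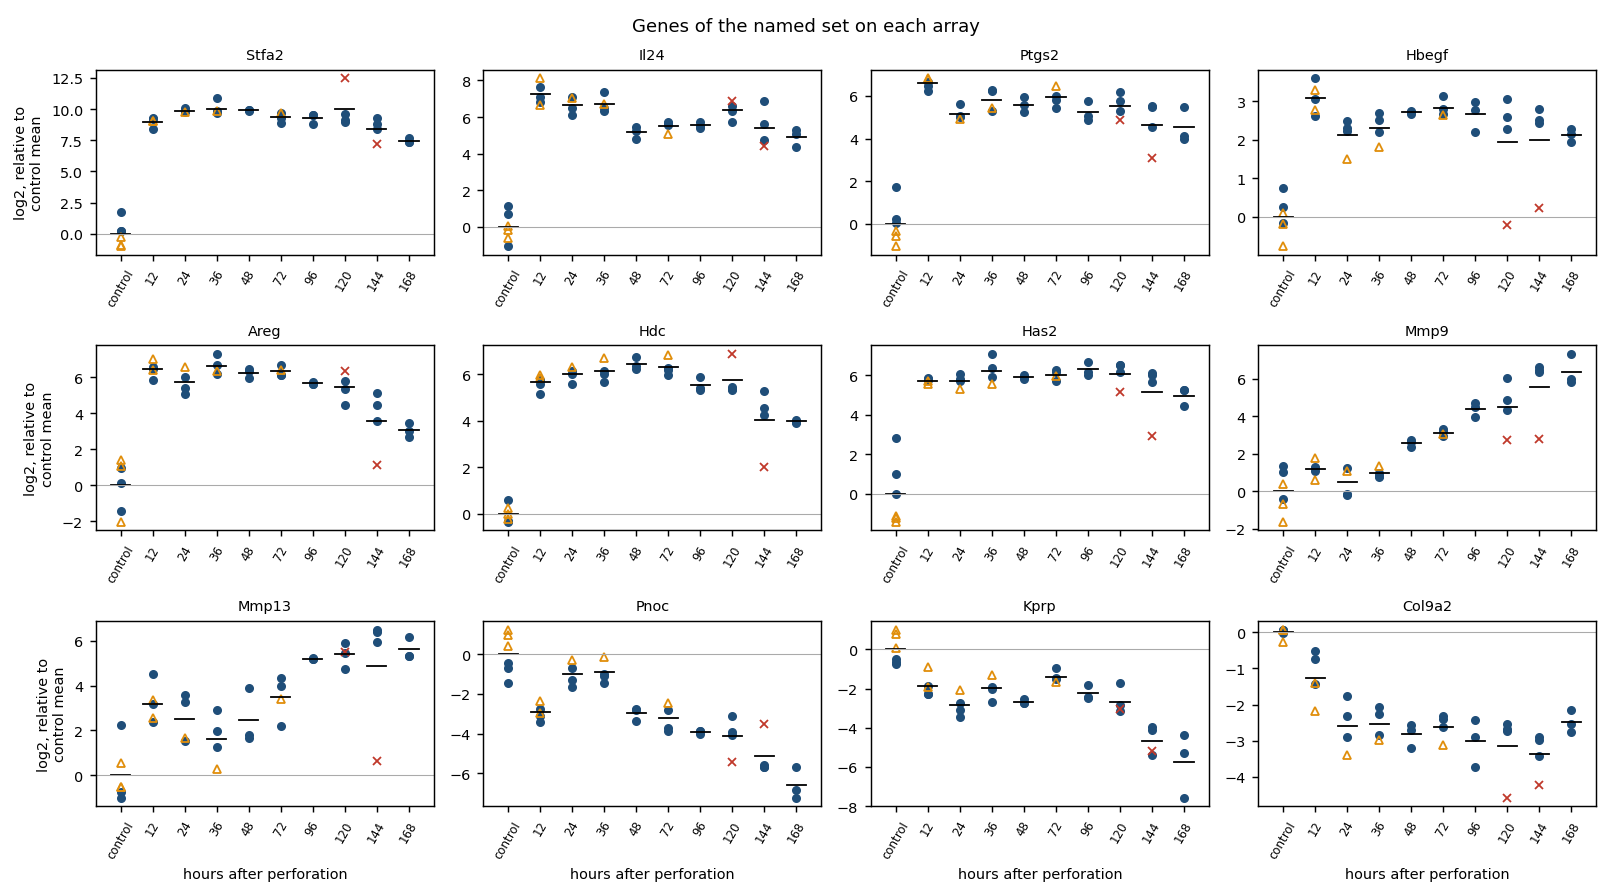
Normalized log2 signal of named genes by hours after perforation, with controls at 0 h, 1 point per array and black bars for group means, blue for pools 1 to 3, orange triangles for pools numbered above 3 and red crosses for the 2 arrays that stand apart. Areg is highest in the first days and Mmp9 climbs to 168 h.

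At 24 h genes of cell division were up. In the cell cycle and mitosis list 27 of 30 rose (27 in-list, median 2.43, camera adjusted p = 7.2e-37). Risers included Ccna2 (2.72 ± 0.33), Ccnb2 (2.05 ± 0.28), Kif20a (2.01 ± 0.30) and Mki67 (2.62 ± 0.55), which encode cyclins, a mitotic kinesin and the Ki-67 proliferation antigen. Of DNA replication genes 17 of 25 rose (23 in-list, median 1.87, camera adjusted p = 1.4e-24), led by ribonucleotide reductase Rrm2 (3.68 ± 0.40, adjusted p = 4.8e-08) and thymidylate synthase Tyms (2.71 ± 0.32). Interleukin 1 beta (Il1b) reached its highest value of the series (4.65 ± 0.58, adjusted p = 7.5e-07), as did the calprotectin subunit S100a8 (4.43 ± 0.51). Stfa2 rose at least 306-fold, Stfa2l1 at least 107-fold and Csta3 at least 79.2-fold, beside Il24 (6.68 ± 0.40) and Nppb (6.61 ± 0.53). The largest falls were in Igsf1 (-4.32 ± 0.62), Ces1d (-4.32 ± 0.63), Akr1c15 (-3.85 ± 0.67), Col10a1 (-3.71 ± 0.61) and Scg5 (-3.53 ± 0.41), which encode an immunoglobulin superfamily glycoprotein, a carboxylesterase, an aldo-keto reductase, the collagen of hypertrophic cartilage and a chaperone of neuroendocrine secretion (Igsf1 probe at chromosome X, 136364654 to 136364713). Cartilage markers fell together: 9 of 14 fell (12 in-list, median -2.30, camera adjusted p = 1.1e-10). Dendritic and Langerhans cell markers rose, as 6 of 13 rose (7 in-list, median 1.05, camera adjusted p = 2.2e-04, adjusted p = 0.0703 with an estimated correlation). The class II genes RT1-Db1 (1.42 ± 0.38), RT1-Da (1.09 ± 0.34) and Cd74 (1.32 ± 0.40) were among them. Of T and NK cell markers 2 of 18 rose (3 in-list, median 0.38, camera adjusted p = 0.0297, adjusted p = 0.534 with an estimated correlation), namely Zap70 (1.17 ± 0.30) and Cd2 (at least 2.49-fold). The laminin chain Lamb3 (0.97 ± 0.30) rose and Tp63 (-0.44 ± 0.28) did not pass. Of fatty acid and sterol synthesis genes 0 of 27 passed limma's test (0 in-list, 7 at an unadjusted p under 0.05, median 0.47, camera adjusted p = 0.0187, adjusted p = 0.475 with an estimated correlation). Sqle (1.13 ± 0.43), Idi1 (0.63 ± 0.47) and Acsl1 (-1.11 ± 0.39) did not pass. Of oxidative phosphorylation genes 1 of 27 rose (1 in-list, median 0.50, camera adjusted p = 0.00115, adjusted p = 0.504 with an estimated correlation). Cytochrome c (Cycs) rose by 1.25 ± 0.35, with Cyc1 (0.88 ± 0.35) short of the threshold. Of B and plasma cell markers 1 of 4 rose (1 in-list, where 1 fell, median -0.03, mean 0.00, rise by camera, camera adjusted p = 0.539). There Fcrla (1.57 ± 0.35) rose and Mzb1 (-1.53 ± 0.63) and Blk (0.46 ± 0.63) did not pass. In all, 2347 of 26133 genes passed limma's test, of which 1338 genes were higher and 1009 lower (1428 and 473 with each array scaled to its median), and the median of all genes lay at -0.24. Among the 24 h changes named, the adjusted p was at most 0.0365 (RT1-Da). With the pool number as a block, which the arrays of these groups bore out, the T and NK cell markers call ended (adjusted p = 0.117, 0.00418 to 0.701 over all alternatives) and so did that of the oxidative stress response (adjusted p = 0.0544, 0.00129 to 0.133 over all alternatives), while skeletal muscle markers (adjusted p = 0.00761, 0.00395 to 0.604 over all alternatives) and Schwann cell and nerve markers (adjusted p = 0.0195, 0.00182 to 0.374 over all alternatives) passed as falls. At 24 h the count was 1526 without 24 h pool 1, 1528 without 24 h pool 3, 4452 without 144 h pool 4 and 6507 without both arrays that stand apart. At 24 h, slide as a fixed block gave 1028 genes, and 25 of the 25 list calls kept their direction, 23 of them past the test.

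At 36 h Serpinb3, Areg and Ptges were at their highest. The squamous cell serpin Serpinb3 rose by 5.18 ± 0.49, adjusted p = 2.2e-09 (chromosome 13, 13340511 to 13340570), amphiregulin (Areg, an EGF receptor ligand) by 6.65 ± 0.56 and prostaglandin E synthase (Ptges) by 4.13 ± 0.38. Stfa2 rose at least 346-fold, adjusted p = 6.6e-17, Stfa2l1 at least 92.8-fold, Csta3 at least 80.5-fold, Il24 by 6.73 ± 0.40 and Nppb by 7.06 ± 0.53. The eicosanoid pathway list moved with Ptges and Ptgs2 (at least 17.3-fold): 4 of 22 rose (4 in-list, median 0.54, camera adjusted p = 0.00215). Macrophage and monocyte markers had risen, as 4 of 22 rose (9 in-list, median 1.07 or 0.77 with bounds, camera adjusted p = 3.3e-07). Ms4a7 (2.95 ± 0.29) and Cd68 (1.53 ± 0.27) were among them and Fcgr2b (0.20 ± 0.39) was not. Of neutrophil markers 4 of 12 rose (4 in-list, median 1.20 or 0.80 with bounds, camera adjusted p = 4.9e-09). The antiapoptotic NF-kB target Bcl2a1 (3.14 ± 0.38) rose too. Of keratinocyte markers 2 of 12 rose (3 in-list, median 0.71, camera adjusted p = 0.0303, adjusted p = 0.470 with an estimated correlation), the 2 being Lypd3 (1.27 ± 0.34) and Serpinb5 (1.54 ± 0.45). Of VEGF, PDGF, IGF and HGF factors 1 of 25 rose and 1 fell (1 and 2 in-list, median -0.28, camera adjusted p = 0.405). Vegfa rose by 2.06 ± 0.51 and Vegfd fell by 1.74 ± 0.47 on the log2 scale, both growth factors of vessels, while Igf1 (-0.27 ± 0.42) and Igf2 (-1.42 ± 0.47) did not pass. Of Schwann cell and nerve markers 4 of 16 fell (7 in-list, where 1 rose, median -0.96, camera adjusted p = 0.00793, adjusted p = 0.0725 with an estimated correlation), among them peripherin Prph (-1.65 ± 0.27). Of melanocyte markers 1 of 6 rose and 1 fell (2 and 1 in-list, median 0.84, camera adjusted p = 0.292). Sox10 (-1.11 ± 0.32), also a Schwann cell factor, fell and Tyrp1 rose (at least 1.41-fold, well above background on 2 of 4 perforated arrays, but -0.04 with normexp background correction), while Tyr (2.00 ± 0.72) did not pass. The largest falls were Igsf1 (-3.01 ± 0.62), Gal (-2.94 ± 0.43), Ces1d (-2.92 ± 0.63) and Smpd3 (-2.78 ± 0.39) and Col10a1, which fell at least 4.69-fold. They encode, besides those named at 24 h, the neuropeptide galanin and neutral sphingomyelinase 2. Respiratory chain subunit Cox7b (1.19 ± 0.29) rose. In all, 1921 of 26133 genes passed limma's test, of which 1184 genes were higher and 737 lower (1083 and 378 with each array scaled to its median, 719 and 1027 with the percentile taken over probes well above background on all arrays), and the median of all genes lay at -0.12. Among the 36 h changes named, the adjusted p was at most 0.0281 (Serpinb5). At 36 h the count was 1221 without 36 h pool 2, 1276 without 36 h pool 3, 3673 without 144 h pool 4 and 5392 without both arrays that stand apart. At 36 h, slide as a fixed block gave 217 genes, and 27 of the 27 list calls kept their direction, 25 of them past the test.

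At 48 h histidine decarboxylase (Hdc), the enzyme that makes histamine, reached its peak with a rise of 6.44 ± 0.42, adjusted p = 3.1e-13 (chromosome 3, 114025082 to 114025141), next to Areg (6.26 ± 0.62) and Nppb (5.76 ± 0.58), Stfa2 (at least 313-fold), Stfa2l1 (at least 108-fold) and Csta3 (at least 85.6-fold). Hdc also counts as a mast cell marker, but of that list 1 of 11 rose (1 in-list, median 0.50, camera adjusted p = 0.0121, adjusted p = 0.0572 with an estimated correlation). The mast cell protease Mcpt1 (Mcpt2) (-0.07 ± 0.43) did not pass. Basal keratinocyte and hemidesmosome genes were at their highest, as 5 of 14 rose (7 in-list, median 1.08, camera adjusted p = 4.3e-04, adjusted p = 0.325 with an estimated correlation). Krt5 (2.02 ± 0.68) and Lamb3 (1.27 ± 0.32) rose, with the keratin 5 partner Krt14 (1.56 ± 0.55) short of the threshold. Of plasminogen activation genes 4 of 11 rose and 1 fell (6 and 1 in-list, median 1.46, camera adjusted p = 3.8e-04, adjusted p = 0.116 with an estimated correlation). Urokinase Plau (3.29 ± 0.78) and Plaur (4.44 ± 0.62) rose and thrombomodulin Thbd (-1.78 ± 0.39) fell. Of FGF family members 1 of 13 rose and 2 fell (1 and 2 in-list, median -0.04, camera adjusted p = 0.855). The FGF carrier Fgfbp1 (2.78 ± 0.62) rose, Fgf13 (-2.42 ± 0.45) and Fgfr2 (-1.58 ± 0.34) fell, and Fgf2 (-0.04 ± 0.98) and Fgf7 (0.41 ± 0.62) did not pass. Transforming growth factor Tgfb1 (2.59 ± 0.69) and the lymphatic and activation marker podoplanin Pdpn (3.57 ± 0.47) rose. Osteoblast and osteocyte markers fell, as 4 of 9 fell (5 in-list, median -1.35, camera adjusted p = 0.00407, adjusted p = 0.0886 with an estimated correlation). Osteocalcin Bglap (-2.90 ± 0.34) and alkaline phosphatase Alpl (-2.09 ± 0.39) were among them. Of red cell and platelet markers 2 of 12 fell (4 in-list, median -1.39, camera adjusted p = 0.0187, adjusted p = 0.438 with an estimated correlation). They were Ahsp (-2.37 ± 0.73) and Epb42 (at least 3.00-fold, well above background on 5 of 6 control arrays). Of glucocorticoid response genes 3 of 12 rose and 3 fell (3 and 6 in-list, median -0.82, camera adjusted p = 0.963), with the sulfotransferase Sult1a1 (-2.86 ± 0.29) down. The vessel gene Angpt1 (at least 2.42-fold) and the endothelial factor Erg (-2.30 ± 0.43) fell and so did the kinase gene Mylk (at least 4.58-fold, well above background on 5 of 6 control arrays). The largest falls were Ces1d (-4.89 ± 0.69), Igsf1 (-4.27 ± 0.68), Cyp2f4 (-3.98 ± 0.48), Gal (-3.93 ± 0.47) and Smpd3 (-3.85 ± 0.43). The sterol enzyme Sqle (1.37 ± 0.47) rose. In all, 3141 of 26133 genes passed limma's test, of which 1426 genes were higher and 1715 lower (1506 and 871 with each array scaled to its median), and the median of all genes lay at -0.23. Among the 48 h changes named, the adjusted p was at most 0.0488 (Sqle). At 48 h the count was 1645 without 48 h pool 3, 1671 without 48 h pool 1, 1624 without 48 h pool 2, 5638 without 144 h pool 4 and 7607 without both arrays that stand apart. At 48 h, slide as a fixed block gave 1864 genes, and 27 of the 27 list calls kept their direction, 20 of them past the test.

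At 72 h Hdc, Areg and Stfa2 stayed high and Timp1 peaked. Hdc (6.33 ± 0.38, adjusted p = 3.2e-14) and Areg (6.34 ± 0.56) were among the largest rises, with Stfa2 (at least 219-fold), Stfa2l1 (at least 86.8-fold) and Csta3 (at least 64.0-fold). The eosinophil ribonuclease gene Rnase3 (6.32 ± 0.54) had risen too. Tissue inhibitor of metalloproteinases Timp1 (4.25 ± 0.49, adjusted p = 8.4e-08) (chromosome X, 12548256 to 12549259) rose. Of protease inhibitors 7 of 18 rose and 2 fell (8 and 2 in-list, median 1.00, camera adjusted p = 6.8e-07, adjusted p = 0.0543 with an estimated correlation). Fibronectin Fn1 (3.15 ± 0.35) and the collagen hydroxylase P4ha3 (2.01 ± 0.61) had risen. Of TGF-beta family genes 5 of 28 rose and 2 fell (5 and 2 in-list, median 0.14, camera adjusted p = 0.0206, adjusted p = 0.365 with an estimated correlation). The SMAD repressor Skil (2.29 ± 0.27) rose. Of glycolysis and hypoxia response genes 8 of 27 rose and 1 fell (10 and 2 in-list, median 0.69, camera adjusted p = 1.4e-04, adjusted p = 0.164 with an estimated correlation). The lactate carrier Slc16a3 (1.20 ± 0.39) rose, with Egln3 (-0.76 ± 0.30) and Ankrd37 (-0.20 ± 0.30) not past the test. In epidermal differentiation 3 of 13 rose (3 in-list, where 1 fell, median -0.15, mean 0.34, rise by camera, camera adjusted p = 0.255). Repetin (Rptn) rose at least 5.76-fold and Aloxe3 (-0.69 ± 0.27) and Asprv1 (-0.11 ± 0.39) did not pass. Of apoptosis and p53 targets 3 of 23 rose and 1 fell (3 and 1 in-list, median 0.37, camera adjusted p = 0.0105, adjusted p = 0.302 with an estimated correlation). Bid (1.29 ± 0.36) rose, Bik (-1.53 ± 0.39) fell and Perp (0.77 ± 0.44) did not pass. Of myofibroblast and contractile genes 1 of 13 rose and 3 fell (2 and 3 in-list, median 0.51, camera adjusted p = 0.664). Mylk (at least 6.93-fold, well above background on 5 of 6 control arrays) and Cnn1 (at least 1.12-fold, well above background on 3 of 6 control arrays) fell. Galanin (-4.17 ± 0.43), Ces1d (-4.55 ± 0.63) and Akr1c15 (-3.75 ± 0.67), Col10a1 (at least 6.11-fold) and Igsf1 were the largest falls. In all, 2935 of 26133 genes passed limma's test, of which 1359 genes were higher and 1576 lower (938 and 696 with quantile normalization, 1816 and 719 with each array scaled to its median), and the median of all genes lay at -0.28. Among the 72 h changes named, the adjusted p was at most 0.0408 (Slc16a3). At 72 h the count was 5485 without 144 h pool 4 and 7342 without both arrays that stand apart. At 72 h, slide as a fixed block gave 2313 genes, and 29 of the 29 list calls kept their direction, 24 of them past the test.

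At 96 h genes that remodel matrix rose beside those of proliferation. Hyaluronan synthase 2 (Has2, chromosome 7, 93264665 to 93264724) rose by 6.29 ± 0.61, adjusted p = 7.2e-09, and the stromelysin Mmp3 (4.69 ± 0.65, adjusted p = 4.8e-06) and collagenase Mmp13 (5.21 ± 0.85) were up. Of matrix metalloproteinases 6 of 23 rose (7 in-list, where 1 fell, median 0.87, camera adjusted p = 1.2e-05). The collagen and processing genes P4ha3 (3.46 ± 0.67), Col5a3 (1.80 ± 0.50) and Col3a1 (2.02 ± 0.64) rose and the cartilage collagen Col11a2 (-3.63 ± 0.42) fell. DNA replication genes Rrm2 (3.98 ± 0.44) and Cdc6 (2.47 ± 0.42) peaked. Of cell cycle and mitosis genes 23 of 30 rose (26 in-list, median 2.08, camera adjusted p = 1.5e-25). Beta-defensin Defb4 (at least 21.5-fold) peaked too, and the chemokine Cxcl3 (3.88 ± 0.53), Rnase3 (6.05 ± 0.59) and Areg (5.67 ± 0.62), Stfa2 (at least 209-fold), Stfa2l1 (at least 68.9-fold) and Csta3 (at least 65.4-fold) stayed high. Of basement membrane genes 3 of 19 rose and 1 fell (3 and 1 in-list, median 0.45, camera adjusted p = 0.0200, adjusted p = 0.551 with an estimated correlation, but median -1.06 with slide as a fixed block). Col18a1 (2.21 ± 0.53) and Nid2 (1.72 ± 0.44) were among the risers. The cartilage genes Col2a1 (-1.80 ± 0.50), Col9a2 (-3.02 ± 0.41) and Snorc (-3.39 ± 0.39) lay below control. The largest falls were Ces1d (-4.56 ± 0.69), Smpd3 (-4.23 ± 0.43), Igsf1 (-4.05 ± 0.68), Akr1c15 (-4.03 ± 0.73) and Pnoc (-3.91 ± 0.52), the last encoding the nociceptin precursor. In all, 2862 of 26133 genes passed limma's test, of which 1287 genes were higher and 1575 lower (1269 and 955 with each array scaled to its median), and the median of all genes lay at -0.20. Among the 96 h changes named, the adjusted p was at most 0.0348 (Col3a1). The 3 arrays of this group lay on 1 slide, shared with 120 h pool 1. At 96 h the count was 1162 without 96 h pool 1, 1391 without 96 h pool 3, 5504 without 144 h pool 4 and 7464 without both arrays that stand apart. At 96 h, slide as a fixed block gave 20 genes, and 26 of the 28 list calls kept their direction, 18 of them past the test.

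At 120 h the neutrophil chemokine Cxcl2 (7.05 ± 0.52, adjusted p = 5.1e-12) (chromosome 14, 18677236 to 18677295) was the highest of the series, and the eosinophil gene Rnase3 (6.36 ± 0.54, adjusted p = 1.3e-10), Stfa2 (at least 345-fold), Stfa2l1 (at least 125-fold) and Csta3 (at least 110-fold) rose with Il24 (6.38 ± 0.40). The matrix genes Fn1 (4.17 ± 0.35), Col1a1 (2.18 ± 0.41), Col3a1 (2.91 ± 0.58) and P4ha3 (4.92 ± 0.61) rose. The fibroblast marker Thy1 (1.20 ± 0.42) was short of the threshold. The metalloproteinases Mmp13 (5.40 ± 0.77), Mmp9 (4.50 ± 0.59) and Mmp23 (1.57 ± 0.40) rose. The coagulation inhibitor Tfpi2 rose at least 3.04-fold and factor V by 1.42 ± 0.36 (F5). The hypoxia genes Slc16a3 (1.99 ± 0.39) and Ankrd37 (1.08 ± 0.30) rose. Middle ear mucosa and ciliated cell markers fell, as 3 of 16 fell (3 in-list, median -0.59, camera adjusted p = 0.00651, adjusted p = 0.194 with an estimated correlation, but median 0.45 with slide as a fixed block and 0.17 with that block and both arrays that stand apart left out). They were Krt19 (-2.33 ± 0.37), Aqp5 (-2.11 ± 0.38) and Bpifa1 (-2.07 ± 0.50). Of sebaceous and hair follicle markers 1 of 6 fell (1 in-list, median -1.40, camera adjusted p = 0.204). It was trichohyalin Tchh (-1.40 ± 0.45), with Mgst1 (-0.80 ± 0.53) and Awat2 (-1.40 ± 1.46) not past the test. Of WNT pathway genes 1 of 23 rose and 6 fell (1 and 6 in-list, median 0.08, mean -0.31, fall by camera, camera adjusted p = 0.341). Wnt6 (-2.67 ± 0.40) and Wnt5a (-0.83 ± 0.23) fell. The red cell genes Alas2 (-2.78 ± 0.72) and Ahsp (-2.40 ± 0.66) fell. The largest falls were Ces1d (at least 21.4-fold), Col10a1 (at least 5.11-fold) and Pnoc (-4.13 ± 0.48), Rasd2 (-3.82 ± 0.36) and Akr1c19 (-3.77 ± 0.33). The endothelial gene Ramp2 (-1.39 ± 0.27) also fell. In all, 2638 of 26133 genes passed limma's test, of which 1220 genes were higher and 1418 lower (1133 and 843 with each array scaled to its median, 862 and 1747 with the percentile taken over probes well above background on all arrays), and the median of all genes lay at -0.08. Among the 120 h changes named, the adjusted p was at most 0.0408 (Tchh). In 120 h pool 4 the medians of the fibroblast, fibrillar collagen, basement membrane, apoptosis and unfolded protein lists were the lowest of the group. At 120 h the count was 4480 without 144 h pool 4 and 6478 without both arrays that stand apart. At 120 h, slide as a fixed block gave 84 genes, and 23 of the 24 list calls kept their direction, 19 of them past the test. Without both arrays that stand apart 2419 of the 2638 genes were still called, and Akr1c19 lay at -3.44.

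At 144 h more genes fell than rose, and 144 h pool 4, the array with the weakest signal, belonged to this group. The largest falls were in Smpd3 (-5.27 ± 0.39), Pnoc (-5.12 ± 0.48), Otos (-5.07 ± 0.43), Cnmd (-4.91 ± 0.47) and Kprp (-4.67 ± 0.45), where Otos encodes otospiralin, Cnmd chondromodulin of cartilage and Kprp a keratinocyte protein. Among the rises were Mmp9 (5.58 ± 0.59, adjusted p = 1.1e-08), Cxcl2 (5.52 ± 0.52), Il24 (5.42 ± 0.40), Has2 (5.16 ± 0.56) and Hdc (4.03 ± 0.38), Stfa2 (at least 113-fold), Stfa2l1 (at least 36.2-fold), Steap1 (at least 19.5-fold, well above background on 3 of 4 perforated arrays) and Csta3. Epidermal differentiation genes fell, as 1 of 13 rose and 7 fell (2 and 8 in-list, median -1.77, camera adjusted p = 0.00163, adjusted p = 0.215 with an estimated correlation). The retroviral-like protease Asprv1 (-2.69 ± 0.39) and lipoxygenase Aloxe3 (-1.99 ± 0.27) were among them. The keratinocyte factor Tp63 (-1.75 ± 0.28) fell. The transcription factors Klf4 (-3.30 ± 0.35) and Egr2 (-2.69 ± 0.39) fell, as did Fgfr2 (-2.18 ± 0.31), Igf2 (-3.07 ± 0.47), Wnt10a (-1.61 ± 0.36), Tgfa (-2.05 ± 0.51), Trib3 (-2.39 ± 0.43) and Bpifa1 (-3.15 ± 0.50). Cartilage and osteoblast markers were at their lowest medians. Of osteoblast and osteocyte markers 1 of 9 rose and 5 fell (1 and 6 in-list, median -2.25, camera adjusted p = 6.2e-05), led by Bglap (-4.45 ± 0.31). Of ribosomal proteins 12 of 34 fell (25 in-list, median -1.23, camera adjusted p = 1.3e-08, adjusted p = 0.363 with an estimated correlation). Rpl14 (-1.97 ± 0.43), Rpl35 (-1.83 ± 0.41) and Rps4x (-0.77 ± 0.22) were among them. The list had a median of -0.15 (camera adjusted p = 0.220) without the arrays that stand apart. Of oxidative phosphorylation genes 3 of 27 fell (2 in-list, median -0.63, camera adjusted p = 0.0462, adjusted p = 0.691 with an estimated correlation, but median -0.21 (reversed by camera) with slide as a fixed block and 0.44 with that block and both arrays that stand apart left out). This turned to a rise without those arrays (median 0.28) and with normexp background correction (median -0.03, higher by camera). Both lists were lowest in 144 h pool 4 of the group's arrays. Proapoptotic Bid (1.92 ± 0.36) rose and Bik (-2.77 ± 0.39) fell. Interferon gene Rsad2 (-2.22 ± 0.56), macrophage receptor Fcgr2b (-2.41 ± 0.39) and T cell gene Cd3g (-1.18 ± 0.28) fell. VE-cadherin Cdh5 (1.69 ± 0.38) rose. Keratinocyte growth factor Fgf7 (2.50 ± 0.56) and the clock gene Npas2 (1.91 ± 0.40) rose. In all, 4820 of 26133 genes passed limma's test, of which 1919 genes were higher and 2901 lower (2502 and 2075 with the percentile taken over probes well above background on all arrays), and the median of all genes lay at 0.03. Among the 144 h changes named, the adjusted p was at most 0.0134 (Rps4x). At 144 h the count was 6574 without 144 h pool 4 and 8720 without both arrays that stand apart, with 3875 of the 4820 among them. Without those arrays Pnoc lay at -5.65, Fgfr2 at -1.93, Igf2 at -2.06, Wnt10a at -0.81, Bpifa1 at -2.26, Rpl14 at -1.25, Rpl35 at -1.17, Bid at 1.77, Fcgr2b at -1.73 and Cd3g at -1.05. At 144 h, slide as a fixed block gave 242 genes, and 20 of the 21 list calls kept their direction with 18 of them past the test.

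At 168 h, the last time, genes of connective tissue and its remodelling were up. Gelatinase B (Mmp9, chromosome 3, 155898499 to 155898558) rose by 6.39 ± 0.64, adjusted p = 7.9e-09, and Mmp13 (5.62 ± 0.85), Mmp3 (4.54 ± 0.65) and Mmp23 (2.22 ± 0.44) rose with it. Of matrix metalloproteinases 11 of 23 rose (13 in-list, median 1.37, camera adjusted p = 1.3e-11). Of matrix glycoproteins and proteoglycans 16 of 31 rose and 1 fell (20 and 2 in-list, median 1.99, camera adjusted p = 1.8e-14). Fn1 (3.61 ± 0.38), Fbn2 (3.40 ± 0.42) and Has2 (4.96 ± 0.61) rose. Of fibrillar collagens and their processing genes 13 of 27 rose and 1 fell (17 and 2 in-list, median 1.64, camera adjusted p = 4.2e-11, adjusted p = 0.0517 with an estimated correlation). P4ha3 (5.05 ± 0.67), Col3a1 (3.53 ± 0.64), Col5a3 (3.09 ± 0.50) and Col1a1 (2.05 ± 0.45) rose. The latent TGF-beta binding protein Ltbp2 (3.50 ± 0.53) and the protease inhibitor A2m (4.88 ± 0.40) peaked. Macrophage and monocyte markers were at their highest, as 14 of 22 rose and 1 fell (15 and 2 in-list, median 1.63, camera adjusted p = 7.6e-13), led by Cd68 (3.39 ± 0.30). Of complement and coagulation genes 13 of 24 rose and 1 fell (14 and 1 in-list, median 1.77, camera adjusted p = 4.6e-09), including C1qc (1.85 ± 0.27) and F5 (2.47 ± 0.39). Of osteoclast markers 3 of 5 rose (3 in-list, median 2.17, camera adjusted p = 4.2e-04). They were Ctsk (2.29 ± 0.71) and Atp6v0d2 (2.17 ± 0.65) and Mmp9, which is also a metalloproteinase list member. Of endothelial markers 8 of 17 rose (8 in-list, median 0.75, camera adjusted p = 7.4e-05, adjusted p = 0.0572 with an estimated correlation), and Cdh5 (2.40 ± 0.42) was up. Of fibroblast markers 5 of 12 rose and 1 fell (7 and 1 in-list, median 1.41, camera adjusted p = 1.9e-04, adjusted p = 0.104 with an estimated correlation), with Thy1 (1.95 ± 0.46). Of adipocyte markers 3 of 12 rose (3 in-list, median -0.42, mean 0.11, rise by camera, camera adjusted p = 0.196). They were the lipid genes Fabp4 (at least 6.75-fold) and Lpl (2.14 ± 0.34) and Cfd (1.81 ± 0.42). The haem oxygenase Hmox1 (3.58 ± 0.49), Igf1 (2.05 ± 0.46), Nid2 (2.56 ± 0.44), Col18a1 (2.55 ± 0.53) and Tubb3 (2.78 ± 0.37) rose. The chemokine Cxcl2 (6.65 ± 0.57), Stfa2 (at least 57.6-fold), Stfa2l1 (at least 19.9-fold), Il24 (4.91 ± 0.44) and Hdc (3.99 ± 0.42) and Steap1 (at least 22.3-fold) were still up, while Serpinb3 (1.35 ± 0.54), Epgn (-0.28 ± 0.33), Ereg (-0.70 ± 0.35) and Tgm1 (-0.57 ± 0.42) no longer passed. Of epidermal differentiation genes 8 of 13 fell (9 in-list, median -1.94, camera adjusted p = 3.8e-06, adjusted p = 0.0572 with an estimated correlation). Kprp (-5.76 ± 0.49) and Aloxe3 (-2.42 ± 0.29) fell. Pnoc fell at least 52.1-fold, adjusted p = 8.4e-11, and Igsf1 (-5.33 ± 0.68), Iqsec3 (-4.98 ± 0.45), Smpd3 (-4.94 ± 0.43), Mepe (-3.97 ± 0.44) and Snorc (-3.85 ± 0.39) fell too. Egln3 (-2.51 ± 0.32), Acsl1 (-2.13 ± 0.43) and Hpgds (-1.87 ± 0.40), Cxcl14 (-2.26 ± 0.34) and Tchh (at least 2.51-fold, well above background on 5 of 6 control arrays) were lower. In all, 2585 of 26133 genes passed limma's test, of which 1150 genes were higher and 1435 lower (1350 and 989 with the percentile taken over probes well above background on all arrays), and the median of all genes lay at -0.16. Among the 168 h changes named, the adjusted p was at most 0.0318 (Ctsk). At 168 h the count was 1293 without 168 h pool 1, 1664 without 168 h pool 2, 1598 without 168 h pool 3, 4802 without 144 h pool 4 and 6430 without both arrays that stand apart. At 168 h, slide as a fixed block gave 2917 genes, and 29 of the 30 list calls kept their direction, 25 of them past the test.

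**Figure D3:**
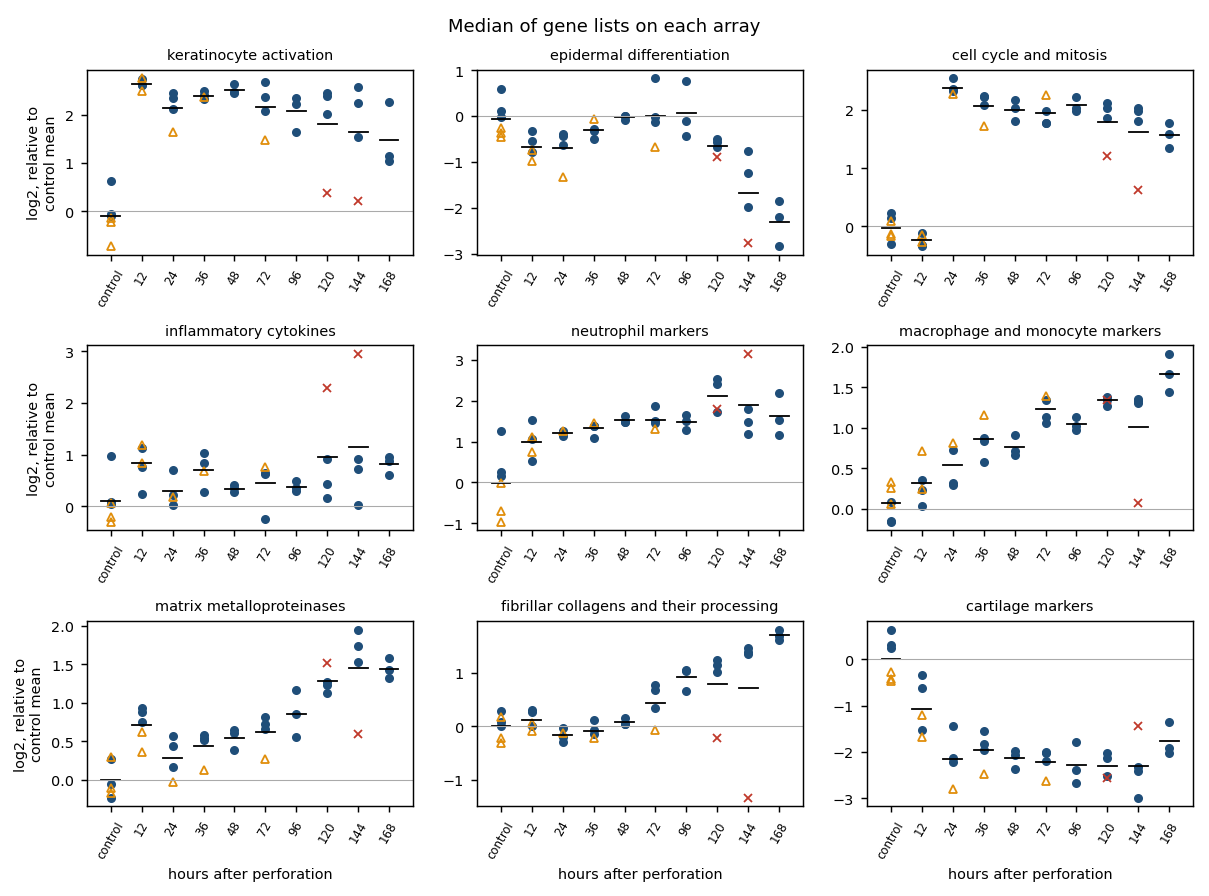
Median log2 value of gene lists by hours after perforation, relative to the mean of the controls at 0 h, 1 point per array and black bars for group means, blue for pools 1 to 3, orange triangles for pools numbered above 3 and red crosses for the 2 arrays that stand apart. The cell cycle list lies near 0 at 12 h and above 1 from 24 h, and the cartilage list lies below 0 from 12 h.

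Between 12 h and 72 h cell division genes rose and early signals such as Nppb fell. Of cell cycle and mitosis genes 21 of 30 rose (28 in-list, median 2.06, camera adjusted p = 1.5e-64). Examples are Ccna2 (2.26 ± 0.35) and Kif20a (2.62 ± 0.31). Rrm2 (2.35 ± 0.41), Rnase3 (6.02 ± 0.56, adjusted p = 1.4e-08) and Fn1 (1.88 ± 0.36) were higher at 72 h and Nppb (-2.66 ± 0.55) and Epgn (-1.77 ± 0.31) lower. Cartilage markers fell further, as 1 of 14 fell (3 in-list, median -1.17, camera adjusted p = 5.2e-07). In all, 378 of 26133 genes passed limma's test, of which 267 genes were higher and 111 lower (317 and 39 with each array scaled to its median, 171 and 118 with the percentile taken over probes well above background on all arrays), and the median of all genes lay at -0.15. Among the 72 h against 12 h changes named, the adjusted p was at most 0.00434 (Nppb). Within slide 5, with both groups, 375 of 378 genes and 17 of 20 lists kept direction, on arrays that made the calls. At 72 h against 12 h the count was 247 without 72 h pool 1, 237 without 72 h pool 2, 881 without 144 h pool 4 and 1474 without both arrays that stand apart. At 72 h against 12 h, slide as a fixed block gave 592 genes, and 20 of the 20 list calls kept their direction, 13 of them past the test. With that block 142 genes were higher and 450 lower.

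Between 72 h and 168 h matrix and fibroblast genes rose while epidermal differentiation and EGF family genes fell. Of matrix glycoproteins and proteoglycans 11 of 31 rose (18 in-list, where 1 fell, median 1.86, camera adjusted p = 1.6e-16), including Fbn2 (3.02 ± 0.45) and Ltbp2 (2.45 ± 0.57). Of matrix metalloproteinases 5 of 23 rose (8 in-list, median 0.92, camera adjusted p = 1.4e-06), including Mmp9 (3.25 ± 0.70, adjusted p = 0.00462). Of angiogenesis genes 3 of 21 rose (12 in-list, median 1.29, camera adjusted p = 3.0e-11). Of fibroblast markers 3 of 12 rose (6 in-list, median 1.51, camera adjusted p = 2.1e-06). Of epidermal differentiation genes 8 of 13 fell (8 in-list, median -2.33, camera adjusted p = 1.4e-14), including Kprp (-4.36 ± 0.53). The EGF family fell, as 5 of 13 fell (5 in-list, median -0.45, camera adjusted p = 5.5e-06), with Areg (-3.29 ± 0.67), Epgn (-2.50 ± 0.35) and Ereg (-2.77 ± 0.38). Serpinb3 (-3.07 ± 0.58) fell too. In all, 596 of 26133 genes passed limma's test, of which 253 genes were higher and 343 lower (109 and 351 with each array scaled to its median, 320 and 222 with the percentile taken over probes well above background on all arrays), and the median of all genes lay at 0.06. Among the 168 h against 72 h changes named, the adjusted p was at most 0.0111 (Ltbp2). With the pool number as a block, which these arrays bore out, the calls of VEGF, PDGF, IGF and HGF factors (adjusted p = 0.127, 3.7e-04 to 0.202 over all alternatives), mast cell markers (adjusted p = 0.0622, 0.0136 to 0.172 over all alternatives), osteoblast and osteocyte markers (adjusted p = 0.127, 0.0287 to 0.696 over all alternatives) and middle ear mucosa and ciliated cell markers (adjusted p = 0.127, 0.00901 to 0.867 over all alternatives) ended, and falls of plasminogen activation (adjusted p = 0.0246, 0.0246 to 0.569 over all alternatives) and ribosomal proteins (adjusted p = 0.0102, 8.1e-04 to 0.975 over all alternatives) passed. No slide held both groups. At 168 h against 72 h the count was 377 without 168 h pool 1, 380 without 72 h pool 2, 259 without 168 h pool 2, 295 without 168 h pool 3, 1437 without 144 h pool 4 and 2402 without both arrays that stand apart. At 168 h against 72 h, slide as a fixed block gave 63 genes, and 20 of the 28 list calls kept their direction, 12 of them past the test. With that block 55 genes were higher and 8 lower.

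From 12 h to 168 h matrix and macrophage genes rose while early response genes fell. Of fibrillar collagens and their processing genes 11 of 27 rose and 2 fell (17 and 2 in-list, median 1.76, camera adjusted p = 7.5e-13), with Col3a1 (3.62 ± 0.66), Col1a1 (2.49 ± 0.47) and P4ha3 (3.90 ± 0.69). Of macrophage markers 9 of 22 rose and 1 fell (12 and 1 in-list, median 1.43, camera adjusted p = 7.1e-11), including Cd68 (2.92 ± 0.30). Of immediate early genes 6 of 26 fell (11 in-list, median -0.98, camera adjusted p = 3.5e-08), with Fosl1 (-3.15 ± 0.55). The EGF family ligands Epgn (-4.27 ± 0.34) and Areg (-3.43 ± 0.64) fell. Nppb fell by 5.24 ± 0.60, adjusted p = 3.8e-07 on the log2 scale. In all, 1102 of 26133 genes passed limma's test, of which 547 genes were higher and 555 lower, and the median of all genes lay at -0.09. Among the 168 h against 12 h changes named, the adjusted p was at most 6.5e-04 (Col1a1). No slide held both groups. At 168 h against 12 h the count was 649 without 168 h pool 1, 609 without 168 h pool 2, 603 without 168 h pool 3, 2204 without 144 h pool 4 and 3323 without both arrays that stand apart. At 168 h against 12 h, slide as a fixed block gave 225 genes, and 21 of the 25 list calls kept their direction, 16 of them past the test.

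The 12 h and 36 h groups were set against those of 24 h and 48 h, which were taken 12 h apart in the day if perforation was done at 1 time of day. The lowest camera p was that of cell cycle genes, where 6 of 30 fell (26 in-list, median -1.12, camera adjusted p = 1.0e-60), with Ccna2 (-1.23 ± 0.26), Ccnb2 (-1.24 ± 0.22) and Kif20a (-1.40 ± 0.23) among them. Of DNA replication genes 0 of 25 passed limma's test (11 in-list, 14 at an unadjusted p under 0.05, median -0.71, camera adjusted p = 2.6e-25). Of circadian clock genes 0 of 17 passed limma's test (4 in-list, 4 at an unadjusted p under 0.05, median 0.00, mean -0.07, fall by camera, camera adjusted p = 0.889). Of chemokines 0 of 25 passed limma's test (3 in-list, 8 at an unadjusted p under 0.05, median 0.54, camera adjusted p = 1.8e-06). Also called were immediate early genes (0.47), osteoblast and osteocyte markers (0.77), red cell and platelet markers (0.90), cartilage markers (0.59), glucocorticoid response (0.25) and EGF family ligands and receptors (0.27) as higher and keratinocyte markers (-0.40), basal keratinocyte and hemidesmosome (-0.30), basement membrane (-0.19) and dendritic and Langerhans cell markers (-0.20) as lower (medians). With an estimated correlation camera still called 5 of the 13, namely cell cycle, DNA replication, chemokines, immediate early genes and osteoblast markers, and fry those and the EGF family. In all, 26 of 26133 genes passed limma's test, of which 1 gene was higher and 25 lower, against 1345 at an unadjusted p under 0.05, and the median of all genes lay at 0.10. The count was 15 without 36 h pool 2, 40 without control pool 2, 17 without 12 h pool 3, 7 without 24 h pool 1, 8 without 24 h pool 2, 6 without 24 h pool 3, 11 without 36 h pool 3, 10 without 48 h pool 1, 53 without 120 h pool 4, 109 without 144 h pool 4, 13 without 12 h pool 4, 14 without 12 h pool 5 and 6 without 36 h pool 4, and limma called 0 genes without 48 h pool 3 or 48 h pool 2 (1016 and 1003 at an unadjusted p under 0.05). It was 251 without both arrays that stand apart. Within slides 8, 9, 5 and 6, 26, 12, 26 and 13 of the 26 genes and 12, 10, 10 and 11 of the 13 lists kept their direction, and slide as a fixed block gave 51 genes with 13 of 13 lists in the same direction.

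Across all times, 4228 of 26133 genes differed among the 10 groups by limma's F test, and Stfa2, Nppb, Il24, Has2, Hdc, Areg, Ptgs2 and Timp1 rose at each of the 9 times while Ces1d, Smpd3, Akr1c15, Cyp2f4 and Snorc fell at each. Lists of keratinocyte activation, inflammatory cytokines, NF-kB targets, antimicrobial defence and neutrophil markers were called higher and that of cartilage markers lower at each of the 9 times and with each of the 5 other scalings, except keratinocyte activation at 168 h with quantile normalization. Genes called at consecutive times overlapped, which shared controls cause in part without any effect. Of the smaller list of each of the 8 pairs, 64.8% to 82.9% of the higher and 57.0% to 83.2% of the lower genes were shared, 8.91 to 15.1 and 6.63 to 20.1 times the overlap of independent lists. In 20 simulations of unchanged groups the adjusted overlap was 0, as few genes are then called whatever the controls. At the unadjusted threshold it was 5.30 to 6.62 times the independent overlap for higher and 5.01 to 6.46 for lower genes. With 3 controls for 1 time and the other 3 for the next, the ratios were 10.3 to 16.5 and 8.59 to 21.4. The F test called 6932 genes without 144 h pool 4 and 9253 without both arrays that stand apart.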

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

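The tests of weak labelling, wrong label and slide 3 for 144 h pool 4, of a wrong label for 120 h pool 4, of carry-over and dilution for the cartilage markers and of slides 4 and 5 for the pools were chosen only after the result was seen.

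144 h pool 4 and 120 h pool 4 stood apart from their groups in correlation and signal, and both lay on slide 3, as 2 of its 4 arrays, which alone took their grid from a file per the headers. For 144 h pool 4 a misplaced grid would raise the correlation at another shift, but the best shift of up to 4 spots gave 0.0179 against 0.338 in place, and smaller misplacement stays open. A wrong label alone would let an array match another group, but the highest correlation was 0.292 for 144 h pool 4 and 0.732 for 120 h pool 4 (with control, against 0.698 with its own group), under the lowest of 0.864 for the other 38 arrays with their own groups. The 168 h arrays of slide 3 correlated at 0.950 or more with the 168 h array of another slide, which argues against a fault of the whole slide for 144 h pool 4 and leaves a fault of part of it open. Weak labelling or hybridisation remains a candidate explanation, as the spike-in probes had their lowest median log2 signal on 144 h pool 4 (3.37) and next on 120 h pool 4 (5.69), a wrong label beside it stays open, and no biological explanation was tested.

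Pools above 3 differed from pools 1 to 3 at 9046 genes (4215 higher and 4831 lower, limma). Camera called the clock (median -0.90), cartilage (-0.71) and basal keratinocyte (-0.54) lists lower in them. This is over control, 12 h, 24 h, 36 h and 72 h (23 arrays), as pool 4 of 120 h and 144 h stands apart. Control pools 4 to 6 differed from 1 to 3 at 1318. Signal near background would leave under 5% of the brightest genes different, but 49.7% of the brightest 0.25 differed, against 25.9% of the dimmest 0.25. Slides 1 to 5 against 6 to 10 stay open, as differences at 144 h and 168 h and in controls correlated at 0.283. Hybridisation on slides 4 and 5 cannot be told apart, as 0 arrays of pools 1 to 3 lay there. Rat sharing was not recorded, and no biological explanation was tested.

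Cartilage markers fell at each time. Slide was argued against, as medians with a slide block and within slides 7 and 4 were at most -0.878. Dilution by arriving or new cells as the whole source would lower other resting cells alike. But Schwann cell and nerve markers, never called higher, lay at least 2.57 SD above cartilage at each time. The fibroblast list lay 1.44 SD above at 12 h, leaving dilution open then. It rose by 168 h, so 2.33 SD or more later cannot decide. Less carry-over of nearby cartilage and bone cannot be told apart. Cartilage and osteoblast list deviations from group means correlated at -0.391. Within groups and pools 1 to 3 or above 3 this was -0.203 (95% interval -0.561 to 0.218). A fall of cartilage gene expression stays open too.

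Other splits of the same arrays into groups of the same sizes were counted in genes called, on the 25892 without missing values, as the real count, the highest other and the splits as large. At 12 h they were 2007, 777 and 1 of 100, at 24 h 2343, 1221 and 1 of 100. At 36 h they were 1914, 790 and 1 of 100, at 48 h 3112, 3318 and 2 of 84. At 72 h they were 2919, 1678 and 1 of 100, at 96 h 2842, 2927 and 2 of 84. At 120 h they were 2614, 6485 and 3 of 100, at 144 h 4768, 6237 and 3 of 100. At 168 h they were 2564, 2865 and 2 of 84. For 72 h against 12 h they were 382, 117 and 1 of 100. For 168 h against 72 h they were 595, 137 and 1 of 35. For 168 h against 12 h they were 1097, 4 and 1 of 56. For 12 h and 36 h against 24 h and 48 h they were 29, 0 and 1 of 100. By the F test they were 4188, 809 and 1 of 100. Splits ignored slide and pool number. Chance is not excluded where another split called more, nor for 12 h and 36 h against 24 h and 48 h. In the latter limma called 0 genes in other splits. At an unadjusted p under 0.05 they gave 41 to 2138 genes against 1341, and 5 of 100, the real one included, were as large. The rest topped all other splits. At 48 h, 96 h and 168 h the highest other split set control pools 4 to 6, on 1 slide, against pools 1 to 3 with the perforated arrays, and a fixed slide block gave 1864, 20 and 2917 genes there. At 120 h and 144 h the highest other splits grouped pool 4 with 3 control arrays, which points to a structure of the samples.

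Differences between times were themselves tested: 378 genes and 20 lists differed between 72 h and 12 h, 596 and 28 between 168 h and 72 h, and 1102 and 25 between 168 h and 12 h.

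Single arrays far from the rest of their group had these Dixon ratios (gap over range). 144 h pool 4: 75th percentile 0.8752, correlation with its group 0.993, share well above background 0.9418, spike-in signal 0.87, B and plasma cell markers 0.8852, T and NK cell markers 0.9799, TGF-beta family 0.9048, basement membrane 0.834, cell cycle and mitosis 0.8424, complement and coagulation 0.9897, fibrillar collagens and their processing 0.9562, fibroblast markers 0.9369, glycolysis and hypoxia response 0.8741, macrophage and monocyte markers 0.9645, matrix glycoproteins and proteoglycans 0.9408, melanocyte markers 0.866, myofibroblast and contractile 0.9186, oxidative phosphorylation 0.9602, plasminogen activation 0.8631, protease inhibitors 0.8811, ribosomal proteins 0.9441, skeletal muscle markers 0.9824, unfolded protein and heat shock response 0.9129, Bid 0.866, Bpifa1 0.8831, Cd3g 0.8368, Egfr 0.8846, Fcgr2b 0.9007, Fgfr2 0.8313, Igf2 0.8466, Mgst1 0.8739, Pnoc 0.9515, Rpl14 0.8687, Rpl35 0.9168, Wnt10a 0.8714. 120 h pool 4: correlation with its group 0.9316, apoptosis and p53 targets 0.9467, basement membrane 0.889, fibrillar collagens and their processing 0.8445, fibroblast markers 0.8514, unfolded protein and heat shock response 0.9279, Akr1c19 0.9339, Tnnt3 0.8312. Control pool 3: keratinocyte markers 0.7414, Awat2 0.6575, Mgst1 0.7621, S100a8 0.6908, Them5 0.6793. 36 h pool 4: antimicrobial defence 0.8812, endothelial markers 0.834, matrix metalloproteinases 0.8456, oxidative stress response 0.8937. Control pool 2: inflammatory cytokines 0.7019, Hpgds 0.7531, Nrg1 0.6263. Control pool 5: interferon response 0.7496, Col9a2 0.7396, Gbp2 0.6479. 24 h pool 4: circadian clock 0.8549, keratinocyte markers 0.9347, oxidative phosphorylation 0.8364. Control pool 1: Myl11 0.783, Tnnt3 0.7819. 12 h pool 2: B and plasma cell markers 0.7917, Ifit1 0.9072. 12 h pool 5: immediate early genes 0.7181, Hsph1 0.745. 24 h pool 2: B and plasma cell markers 0.8462, Cd2 0.8849. 72 h pool 1: DNA replication 0.8363, inflammatory cytokines 0.8563. 72 h pool 2: immediate early genes 0.8849, Col10a1 0.9663. 72 h pool 4: 75th percentile 0.8397, EGF family ligands and receptors 0.9251. Control pool 4: Otos 0.7356. 12 h pool 1: apoptosis and p53 targets 0.7736. 12 h pool 3: Stfa2 0.7198. 12 h pool 4: Mt1 0.8194. 144 h pool 3: Bglap 0.843. 36 h pool 1: Tyrp1 0.9033. 36 h pool 2: Stfa2 0.8601. 72 h pool 3: myofibroblast and contractile 0.8463. Chance marks about 1 in 20 groups, against 6 of 28 array measures, 43 of 378 list medians and 34 of 339 named genes here.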

How the results depend on the processing

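The alternatives that leave out both arrays that stand apart or the 4 dimmest arrays, that put pools above 3 in a block, and that take the percentile over common probes were chosen after seeing the data. Counts are of genes past limma's test unless lists are named, times are against control unless another time is named, and between times means 72 h against 12 h, 168 h against 72 h and 168 h against 12 h in order. Alternate times are 12 h and 36 h against 24 h and 48 h, and lists that reversed in camera's direction are given with the median log2 change under that alternative, which may keep its sign. The cause was not tested except where fewer arrays or genes explain a change by construction.

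Leaving out each array in turn gave 1392 to 3710 at 12 h, 1526 to 4452 at 24 h, 1221 to 3673 at 36 h, 1624 to 5638 at 48 h, 2086 to 5485 at 72 h, 1162 to 5504 at 96 h, 2075 to 4480 at 120 h, 3796 to 6574 at 144 h and 1293 to 4802 at 168 h. Single arrays left out gave 237 to 881 for 72 h against 12 h, 259 to 1437 for 168 h against 72 h, 603 to 2204 for 168 h against 12 h, 0 to 109 for alternate times and 3509 to 6932 by the F test. The 0 came without 48 h pools 2 and 3 (1003 and 1016 at an unadjusted p under 0.05), the highest counts without 144 h pool 4. Leaving out both arrays that stand apart gave 5096, 6507, 5392, 7607, 7342, 7464, 6478, 8720 and 6430 at the 9 times in order. Without the pair there were 1474, 2402 and 3323 between times, 251 for alternate times and 9253 by the F test. Reversed at 144 h were oxidative phosphorylation (0.28) and unfolded protein and heat shock response (0.83). Leaving out the 4 dimmest arrays gave 5289, 6178, 5277, 7758, 7297, 7553, 6486, 8768 and 6877 at the 9 times in order. Without the 4 there were 1358, 2626 and 3135 between times, 253 for alternate times and 9116 by the F test. Reversed at 144 h were oxidative phosphorylation (0.24) and unfolded protein and heat shock response (0.80). Array weights gave 5330, 7754, 6728, 10004, 6688, 10230, 10737, 11067 and 8258 at the 9 times in order. The weights also gave 2561, 6718 and 7334 between times, 2878 for alternate times and 13734 by the F test. Only pools 1 to 3 gave 3653, 5133, 4613, 6133, 4630, 6746, 6379, 7722 and 5535 at the 9 times in order. These pools also gave 1372, 3040 and 4418 between times, 445 for alternate times and 9201 by the F test. Reversed at 144 h were interferon response (0.54), oxidative phosphorylation (0.40) and unfolded protein and heat shock response (0.64). The lowest array weights were 0.0235 and 0.0550.

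Normexp background correction gave 1027 at 12 h, 1498 at 24 h, 1096 at 36 h, 1764 at 48 h, 1203 at 120 h, 2262 at 144 h and 1637 at 168 h. With normexp there were 230 for 72 h against 12 h, 696 for 168 h against 12 h, 10 for alternate times and 2367 by the F test. It reversed Tyrp1, perforated 36 h against control (-0.0368). Ribosomal proteins reversed at 24 h (0.32), at 72 h (0.35) and at 96 h (0.45). Lists reversed at 144 h were oxidative phosphorylation (-0.0327) and unfolded protein and heat shock response (0.17). Quantile normalization gave 1249 at 12 h, 1427 at 24 h, 1209 at 36 h, 1914 at 48 h, 1634 at 72 h and 1593 at 96 h. Quantiles also gave 190, 277 and 672 between times, 0 for alternate times and 2662 by the F test. Scaling to the array median gave 1323 at 12 h and 10 for alternate times. The deposited value table gave 1726 at 120 h and 2809 at 144 h and 15 for alternate times. Without the filter on dim probes the test gave 10 for alternate times. The 0 stands beside 922 genes at an unadjusted p under 0.05. The percentile over common probes, the mean of all probes of a gene, the stricter filter, the fit without the intensity trend and the scan batch as a block moved 0 of their counts by more than 1.5 times.

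A fixed slide block gave 1028 at 24 h, 217 at 36 h, 1864 at 48 h, 20 at 96 h, 84 at 120 h and 242 at 144 h. This block also gave 592, 63 and 225 between times and 51 for alternate times. Lists reversed at 96 h were basement membrane (-1.06) and skeletal muscle markers (0.35). At 120 h it reversed middle ear mucosa and ciliated cell markers (0.45). Lists reversed at 144 h were interferon response (0.55) and oxidative phosphorylation (-0.21). At 168 h it reversed keratinocyte markers (0.22). Lists reversed for 168 h against 72 h were basal keratinocyte and hemidesmosome (0.55), cell cycle and mitosis (0.009), DNA replication (0.34), protease inhibitors (-0.0142), glycolysis and hypoxia response (0.72), oxidative phosphorylation (0.29), unfolded protein and heat shock response (0.69), apoptosis and p53 targets (0.21) and keratinocyte markers (0.12). For 168 h against 12 h it reversed epidermal differentiation (-0.44), NF-kB feedback and targets (-0.26), interferon response (0.58), oxidative phosphorylation (0.42), fatty acid and sterol synthesis (-0.44), unfolded protein and heat shock response (0.58), ribosomal proteins (0.64) and keratinocyte markers (1.00). Slide as a random block gave 785 at 96 h, 1627 at 120 h and 4818 at 168 h and 99 for alternate times. Both left out with a slide block gave 5482 at 12 h, 4639 at 24 h, 6119 at 48 h, 6102 at 72 h, 89 at 96 h, 309 at 120 h and 2428 at 144 h. In that fit there were 2780, 140 and 483 between times and 984 for alternate times. A reversal at 96 h was angiogenesis and endothelial activation (-0.93). At 120 h it reversed basal keratinocyte and hemidesmosome (0.62) and middle ear mucosa and ciliated cell markers (0.17). Lists reversed at 144 h were interferon response (1.29), oxidative phosphorylation (0.44), unfolded protein and heat shock response (0.78), apoptosis and p53 targets (0.16) and keratinocyte markers (0.57). Both left out with pools above 3 as a block gave 6324, 7673, 6384, 7948, 8758, 8272, 7304, 9473 and 6943 at the 9 times in order. This 2-level block also gave 2322, 3276 and 4092 between times, 378 for alternate times and 10656 by the F test. Reversed at 144 h were interferon response (0.45), oxidative phosphorylation (0.41) and unfolded protein and heat shock response (0.72). Both left out with the percentile over common probes gave 4667, 6252, 5819, 7023, 7228, 7055, 6166, 8119 and 5921 at the 9 times in order. The same fit gave 1515, 2126 and 2826 between times, 197 for alternate times and 8831 by the F test. Reversed at 144 h were oxidative phosphorylation (0.46), unfolded protein and heat shock response (1.01) and apoptosis and p53 targets (0.34). A fit of the groups compared alone gave 1048 at 120 h and 778 at 144 h. This smaller fit also gave 929 for 168 h against 72 h, 3045 for 168 h against 12 h and 271 for alternate times. The consensus correlation within slides was 0.406.

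The pool number as a replicate block gave 2030 at 48 h. Of named gene and list results, 884 stayed on their side of the threshold with that block, 36 newly passed and 28 no longer did. Outside 24 h, where pairing was weak, and 168 h against 72 h, the pool numbers did not pair the arrays. In all, 36 of 88 arrays correlated best with their own number. Camera with an estimated correlation gave 104 lists against control, 29 between times and 5 for alternate times. Fry gave 6 lists for alternate times. The counts here were 238 lists against control, 73 between times and 13 for the last contrast.

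Over single genes, 234 of 246 named results stayed on their side of the threshold with quantile normalization, 213 with normexp and 155 with a fixed slide block, and 5 had no value under the stricter filter. The F test has no value for a fit of the groups compared alone. Simulated changes of 1, 2 and 3 log2 were recovered for 16.4%, 68.7% and 84.8%. Signal over background was not varied there.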

Other observations

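The tests of the 12 h group alone, of slide as the whole source and of time of day were chosen only after the result was seen. The cell cycle and mitosis list was lower at 12 h and 36 h than at 24 h and 48 h (median -1.12). Slide as the whole source was argued against, as the median was -1.17 with slide as a fixed block and -2.62 within slide 8, which held 12 h and 24 h arrays, though 2 of 4 slides with arrays of both sides, which held no 12 h array, had no lower median. Time of day as the whole source would lower 36 h as much as 12 h. Against control the list median was -0.24 at 12 h, 2.38 at 24 h, 2.07 at 36 h and 2.00 at 48 h as the mean of the arrays, so 36 h lay 14.2 SD of the arrays above 12 h. The circadian clock list's median absolute difference lay at percentile 75.1 of random lists. The 12 h group alone is a candidate explanation, as 36 h lay -0.121 from the mean of 24 h and 48 h, within the arrays' SD of 0.162.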
